A study of Mus musculus with 6 samples.

How the data were processed

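The series holds 6 RNA sequencing libraries from 3 mouse SCLL cell lines, each treated for 24 h with the FGFR inhibitor BGJ398 or with DMSO. Per the labels' protocols, the cultures are named BBC2, ZNF112 and BCRF8C, libraries followed standard Illumina procedures, and the RNA was total RNA. Selection of poly(A) RNA, read length, strandedness and depth are not given in the sources used here, nor are the fusion partners of FGFR1 in each line. The doses of 30, 3 and 1.5 nM were assigned to BBC, ZNF and BCRF8C by the order of the protocol's list, which is an assumption. The labels name 1 library per line and agent and no repeat cultures.

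The authors deposited 1 table of FPKM values (fragments scaled by transcript length and by mapped fragments) with 17169 gene entries and 6 columns, and each column name matched the title of 1 sample, so 0 value columns were left unmapped. Per the submitters' processing notes, bcl2fastq and TopHat2 (version 2.0.12) were used with the genome build NCBIM37. The program that estimated FPKM, its annotation and any filter on genes are not given in the sources used here. Depth is unknown. Low values of genes with a single exon and transcript, multiplied by their length, were searched for steps of whole reads. The strongest periodicity was 0.228 in the ZNF library with BGJ398, where values without steps reach 0.228 at the 95th percentile of simulations, and lay below the limit of each library in the other 5. Read steps were therefore not detected, and no interval for counting error was computed. Gene symbols, identifiers and loci were taken from the table, and starts were raised by 1, because end minus start equalled the annotated gene length for 6377 of the 15944 entries matched by identifier to GENCODE vM21 and that length minus 1 for 166. That annotation is of another build and gave only lengths and GC content. In all, 548 entries shared a symbol with another entry, and the entry with the highest mean FPKM stood for the symbol in lists and named genes.

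The values show that the table holds a selection of genes. Every entry listed in BBC reached about 1.02 FPKM in a BBC library, and 14 were at 0 in both BBC libraries. The ZNF libraries were both at 0 for 3185 entries and the BCRF8C libraries for 1640, always in pairs, while BBC had 732 entries at 0 in DMSO alone and 318 at 0 with BGJ398 alone. Such zeros can be failed estimates and were described as listed at 0. Values of 0.001 FPKM in ZNF and BCRF8C were the lowest above 0. Genes without an entry were not analysed here.

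Values were analysed as log2(FPKM + 1) without rescaling. Across lines, genes with a mean of at least 1 FPKM over the 6 libraries (14232) were tested with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes with an intensity trend), BGJ398 against DMSO, with the cell line as a block. P-values were two-sided, adjusted by Benjamini-Hochberg over all genes tested and called at an adjusted p under 0.05. Every adjusted p of a gene or list in the text comes from limma, its camera test or its fry test. The block left 2 residual degrees of freedom per gene, and an exact sign-flip test of 3 pairs cannot go below p = 0.25, so no such test was made beside limma. Camera with an estimated correlation was run as deposited and with the expression trend removed. That version tests on the 2 residual degrees of freedom and so had little power here. No source says that the libraries came from repeated cultures, so p-values measure the spread between 3 different lines at 3 different doses.

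The line paired the libraries, since both libraries of a pair come from the same cell line. Deviations from the group means correlated within a line at 0.454 in BBC, 0.541 in ZNF and 0.549 in BCRF8C, against at most -0.209, -0.179 and -0.280 with another line. Deviations from a group mean cancel out, so a positive value within a line makes those with other lines negative on balance, and the contrast is partly built in.

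The comparisons were of genes and gene lists across the lines, genes and gene lists within a line, agreement of the lines, and differences between the lines. Camera (preset correlation 0.01) tested lists with at least 5 tested members, adjusted over the lists. The 25 lists were FGF receptors and ligands, ERK feedback and immediate early genes, STAT5 targets, MYC and its targets, ribosome biogenesis, S phase, G2 and mitosis, FOXO targets, p53 targets, the BCL2 family, glycolysis, cholesterol synthesis, ATF4 and amino acid supply, interferon response, NF-kB targets, MHC class II, Notch targets, mast cell and cytokine receptors, markers of the B, T, myeloid, erythroid and stem cell lineages, plasma cell genes, and stromal markers. Several genes stand on more than 1 list, such as Myc, Rag1, Ldha and Bax. Within a line, genes with a mean of at least 1 FPKM over its 2 libraries were counted when at least 2-fold apart. The median of each list was placed among 10000 random lists of the same size matched in 20 classes of expression, and lists below the 2.5th or above the 97.5th percentile were counted as outside the range. These describe 2 libraries and carry no p-value. Agreement was measured by correlations across genes and by shared genes beside the number that independent lists would share. A gene was specific to a line with at least 10 FPKM in both its libraries and at least 10-fold above the highest of the other 4.

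Named genes followed a rule. It took Fgfr1 and Myc, and the 10 largest rises and falls across lines among called genes with the same direction in all 3 lines. Within a line it took the 6 highest and 6 lowest ratios at a mean of at least 5 FPKM. For each pair of lines it took the 4 genes with the largest opposite ratios, for each line the 6 most specific genes, and from each list up to 4 members with the largest mean ratio, or for lineage lists the 4 highest in DMSO. Unnamed genes, receptor segments, mitochondrial genes and small RNAs were passed over and counted only; the symbol patterns for these also took further clone names and small RNAs such as 7SK and Y RNAs, which were added after seeing the data. Some genes the rule took are not reported here. The tests, lists, thresholds and named-gene rule were fixed before the data were examined.

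Also fixed then as other settings were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, no replicate block, each line left out in turn, eBayes without the trend or robust, an added ratio limit, camera with an estimated correlation, fry, other folds, and other limits for specific genes. Chosen after seeing the data were the restriction to genes listed in all 3 lines, the removal of the loess trend (span 0.3) of the ratio on mean expression within each line, and the combinations of these with each other and with quantile normalization.

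The methods were tested on simulated data. With the real spread of each gene and 200 of 14232 genes changed, 100 at a log2 change of 1 and 100 at 2, the test across lines recovered 0% at either size and made 0 false calls. With the spread of every gene at the median spread divided by 3 it recovered 100% at both sizes, with 10 false calls. Camera called 1 list, the 1 that had been shifted, which stood at percentile 0 within a line, while 3 other lists fell outside the range by chance. Simulated genes varied independently, whereas the estimated correlation in the data was 0.92 for ribosome biogenesis. The simulation therefore does not show how often camera calls correlated lists falsely. Trend removal left a median of at most 0.154 in size in any expression class and recovered the simulated changes with a correlation of 0.996. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.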

Results

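Transcript levels were profiled by sequencing in 3 mouse cell lines, named BBC, ZNF and BCRF8C in the sample titles. The lines were derived from the bone marrow of Balb/c mice with stem cell leukemia and lymphoma (SCLL), a blood cancer driven by fusion kinases that carry the kinase end of the fibroblast growth factor receptor FGFR1. Each line was grown for 24 h with BGJ398 (infigratinib), a small molecule inhibitor of FGFR kinases, or with its solvent DMSO. A single library was made per line and agent, so 3 libraries were of BGJ398, 3 were of DMSO, and within a line there were no replicates. If the doses in the protocol follow the order in which the lines are listed there, BBC received 30 nM, ZNF 3 nM and BCRF8C 1.5 nM, and a dose and its line cannot be separated. The values were FPKM for 17169 gene entries, and the sequencing depth behind them is unknown. Log2 ratios below are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

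In DMSO the libraries of BBC, ZNF and BCRF8C listed 16423, 13984 and 15529 gene entries above 0. Over the 14232 entries with a mean of at least 1 FPKM in the 6 libraries, their median values were 9.95, 8.36 and 9.03 FPKM. With BGJ398 the medians of the same entries were 4.53, 6.47 and 4.92 FPKM. The numbers of entries with at least 10 FPKM went from 7096 to 3766 in BBC, from 6566 to 5321 in ZNF and from 6823 to 3826 in BCRF8C. Genes used by every cell, chosen after their values were seen, were lower too. Actb, which encodes cytoplasmic actin, went from 3137 to 633 FPKM in BBC, from 1612 to 667 in ZNF and from 2984 to 508 in BCRF8C, a mean log2 ratio of -2.04 as deposited (adjusted p = 0.0686), -0.68 after quantile normalization and -0.38 with the expression trend removed. The glycolytic enzyme gene Gapdh went from 318 to 47.3, from 405 to 203 and from 1227 to 163 FPKM, with mean ratios of -2.21 (adjusted p = 0.0380), -0.75 and -0.50 on the same scales. Entries nearly silent in DMSO (under 0.5 FPKM) but above 1 FPKM with BGJ398 numbered 2330 in BBC, 2287 in ZNF and 3686 in BCRF8C, against 521, 117 and 229 in the opposite direction. The range of values was therefore narrower in all 3 BGJ398 libraries, and library and agent cannot be separated in this design. Over the 14232 entries tested across lines, the median log2 ratio was -0.69 as deposited, 0.03 after median-of-ratios scaling, -0.09 after quantile normalization and 0.03 after the trend of the ratio on expression was removed within each line.

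**Figure D1:**
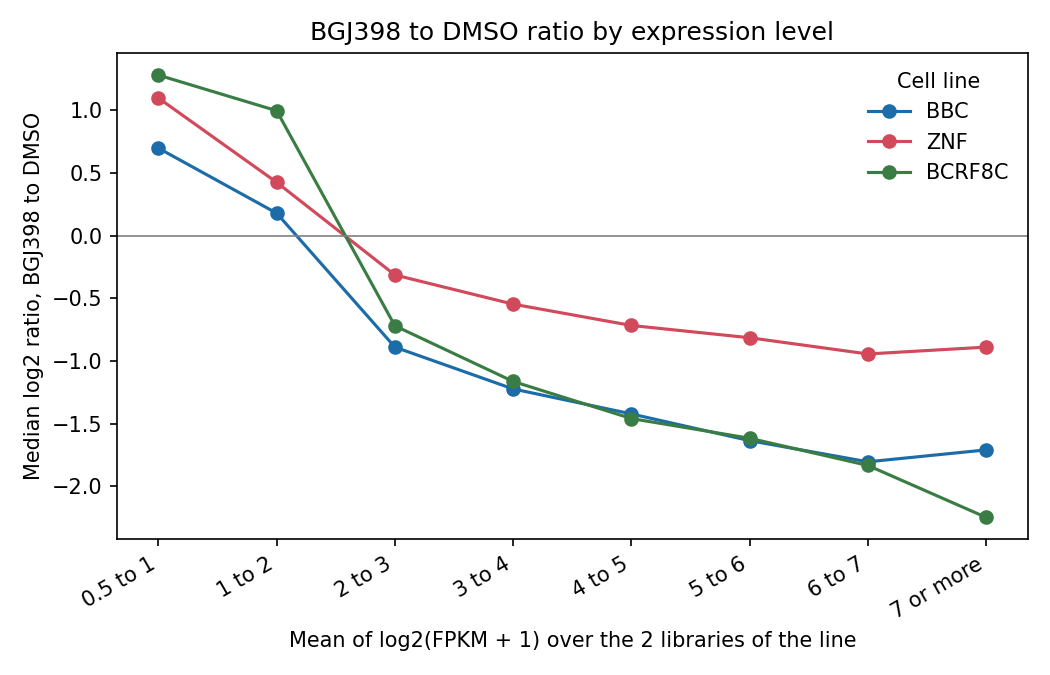
Median log2 ratio of BGJ398 to DMSO (vertical axis) in classes of mean log2(FPKM + 1) over the 2 libraries of a line (horizontal axis), with 1 coloured line of points per cell line. In BBC the median went from 0.70 in the lowest class to -1.71 in the highest, in ZNF from 1.10 to -0.89 and in BCRF8C from 1.28 to -2.25. Nearly all listed entries reach about 1.02 FPKM in a library of BBC and about 0.9 in one of ZNF or BCRF8C. The lowest class therefore holds almost only entries whose 2 values differ, which enlarges its medians. In the class from 2 to 3 the medians were -0.89, -0.31 and -0.72.

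The design text asks how the transcriptomes of SCLL lines differ with and without FGFR1 inhibition. Across the 3 lines, genes of sterol and amino acid synthesis, glycolytic enzymes, MYC targets and replication genes fell, as did single histone genes, and a smaller set of genes, led by the ubiquitin ligase gene Mid1, rose. No list held histone genes, and each of the other gene lists behind this lost its call (adjusted p = 0.725 with an estimated correlation), and with the expression trend removed 0 genes passed in limma (3084 at an unadjusted p under 0.05). Camera with an estimated correlation rests on 2 residual degrees of freedom and had little power, so calls lost there do not show that a list was unchanged. Fgfr1 itself (ENSMUSG00000031565, chromosome 8, 26624126 to 26686186 in NCBIM37) went from 36.7 to 23.3 FPKM in BBC, from 12.9 to 10.1 in ZNF and from 0.510 to 2.54 in BCRF8C, a mean log2 ratio of 0.09 ± 0.997 (SD, n = 3 lines) with a limma adjusted p = 0.870. Its value covers the whole gene and does not separate a fusion transcript from the normal one. Myc (ENSMUSG00000022346, chromosome 15, 61816946 to 61821929), a growth-promoting transcription factor, went from 71.3 to 5.66 FPKM in BBC, from 63.2 to 48.6 in ZNF and from 64.4 to 20.01 in BCRF8C. At a mean log2 ratio of -1.82 ± 1.54 it did not pass the test (adjusted p = 0.0552). Its ratios with the expression trend removed were -1.98 in BBC, 0.49 in ZNF and -0.01 in BCRF8C, so only in BBC did it stay clearly lower. Those of Fgfr1 were 0.92, 0.25 and 0.13.

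In total 5236 of 14232 genes changed in the limma test with the line as a block at an adjusted p under 0.05, 941 upward and 4295 downward (82.0% downward). Of these, 5165 went the same way in all 3 lines. On simulated data with the real spread and 200 changed genes, the same test recovered 0% of log2 changes of 1 or 2. This limits what the count and the single limma calls at adjusted p = 0.0348 can show about a gene on its own. The Benjamini-Hochberg adjustment depends on the number of small p-values. The simulation therefore does not show what the test detects when many genes shift together. In all, 7812 genes had an unadjusted p under 0.05, and 7927 (55.7%) were lower with BGJ398 in all 3 lines while 2197 were higher in all 3. The count and its direction depended on the scaling: 14 genes passed after median-of-ratios scaling (13 up, 1 down), 3 after quantile normalization (2 up, 1 down) and 0 with the expression trend removed (3084 at an unadjusted p under 0.05). Among genes listed in all 3 lines 366 passed with the trend removed (316 up, 50 down) and 394 after quantile normalization (342 up, 52 down). It also depended on the samples and the pairing, with 0 genes without BBC (2991 at an unadjusted p under 0.05), 1648 without BCRF8C and 7 without the line as a block.

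Among called genes that could be named, the 10 largest falls were all genes of the Hist1 clusters, which encode the core histones made during DNA replication. Hist1h4j (ENSMUSG00000067455, chromosome 13, 21826903 to 21827329) fell by 4.24 on the log2 scale (SD 1.77, n = 3 lines), from 757 to 51.1 FPKM in BBC, from 1179 to 183 in ZNF and from 754 to 9.54 in BCRF8C, with a limma adjusted p = 0.0348. Hist1h4k (-4.02 ± 1.83), Hist1h4b (-3.64 ± 1.03), Hist1h2bj (-3.58 ± 1.55), Hist1h2bk (-3.56 ± 1.26), Hist1h4n (-3.47 ± 2.21), Hist1h3h (-3.43 ± 0.89), Hist1h2bg (-3.39 ± 2.14), Hist1h2ah (-3.38 ± 1.22) and Hist1h2bm (-3.35 ± 1.22) followed, with adjusted p between 0.0348 and 0.0350. Genes of the same histone type are near-identical copies, so the value of each is uncertain, and many histone transcripts carry no poly(A) tail. After quantile normalization the 10 ratios remained below 0, between -3.01 for Hist1h4j and -2.05 for Hist1h2bm, with no adjusted p under 0.05.

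Among the rises, Mid1 (ENSMUSG00000035299, chromosome X, 166123129 to 166443668), a microtubule-associated ubiquitin ligase, went from 226 to 656 FPKM in BBC, from 6.27 to 213 in ZNF and from 1.43 to 77.0 in BCRF8C, a rise of 3.81 ± 1.97 on the log2 scale (adjusted p = 0.0348). The zinc finger gene Zfp488 (3.18 ± 1.38), Pkib, which encodes an inhibitor of protein kinase A (3.04 ± 1.33), and Fgd4, a guanine nucleotide exchange factor gene (3.01 ± 1.18), rose at the same adjusted p. So did Zfp353, another zinc finger gene (2.96 ± 1.41), and Fstl1, which encodes a secreted glycoprotein (2.91 ± 1.68). The other 4 were the pseudogenes Fau-ps2 (3.53 ± 2.18) and Speer7-ps1 (2.88 ± 1.88) and the receptor genes Olfr613 (3.40 ± 1.58) and Vmn1r58 (2.98 ± 0.99). Reads of such genes can be shared between copies, so these values are uncertain. All 10 ratios were larger after quantile normalization, from 3.36 for Speer7-ps1 to 4.60 for Mid1, and none passed there. Of the 5236 changed genes, 993 were unnamed, segment or small RNA genes and are only counted.

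**Figure D2:**
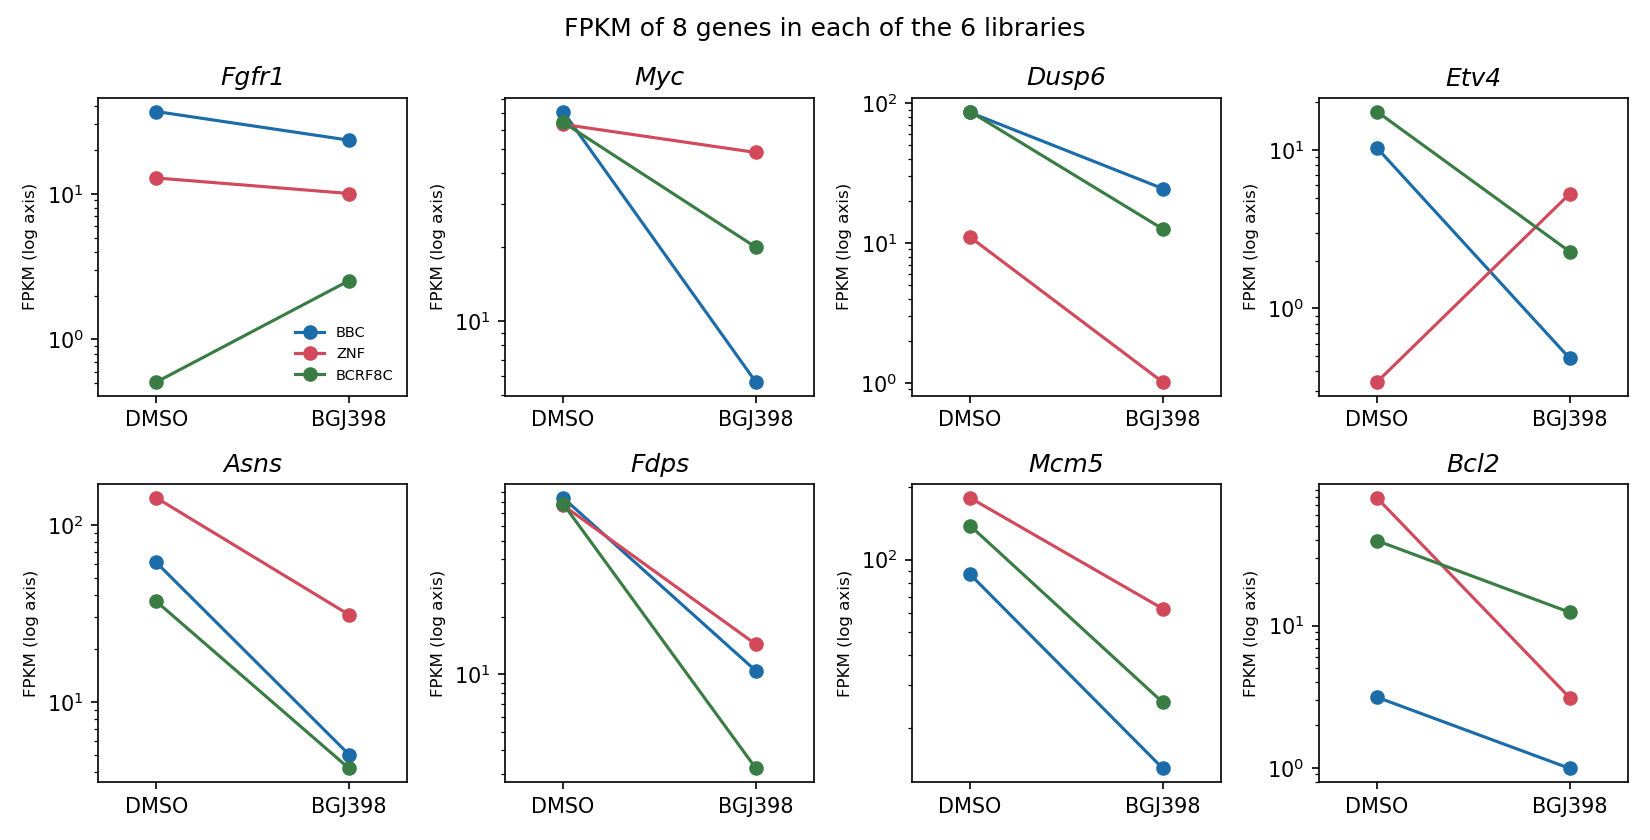
FPKM (vertical axes, logarithmic) of Fgfr1, Myc, Dusp6, Etv4, Asns, Fdps, Mcm5 and Bcl2 in the DMSO and BGJ398 library of each line, with 1 point per library and the 2 libraries of a line joined. Dusp6, Asns, Fdps and Mcm5 were lower with BGJ398 in all 3 lines, and their mean ratios were below 0 after quantile normalization without passing there (adjusted p from 0.107 to 0.193). With the expression trend removed Dusp6 was at -0.09 in BBC. Etv4 was lower in BBC and BCRF8C and went from 0.342 to 5.29 FPKM in ZNF.

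Feedback genes of the ERK cascade, which FGF receptors drive, fell in part. Dusp6 (ENSMUSG00000019960, chromosome 10, 98725865 to 98730122), a phosphatase that acts on ERK, went from 85.8 to 24.5 FPKM in BBC, from 11.1 to 1.01 in ZNF and from 87.1 to 12.6 in BCRF8C (-2.35 ± 0.51, adjusted p = 0.0348), and the related phosphatase gene Dusp4 fell by 1.84 (SD 0.56, n = 3 lines, adjusted p = 0.0348). The immediate early genes Junb (-1.92 ± 1.71, adjusted p = 0.0550) and Ier2 (-1.86 ± 1.65, adjusted p = 0.0528) did not pass. Of 22 tested members, 6 fell, 5 when adjusted over the list alone, and 16 did not pass. That share is not above the one over all genes, of which 4295 of 14232 fell. The median of the list (-0.63) lay 0.06 above that of all genes. Camera, which compares a list with the other tested genes, gave an upward direction although median and mean (-0.51) were below 0 (adjusted p = 0.794). Of 13 STAT5 targets, genes switched on by cytokine signals, 7 fell over all genes and over the list alone, among them Ccnd3, a G1 cyclin gene (-2.47 ± 0.68). Socs1, an inhibitor of cytokine signalling (-2.39 ± 1.19), the cytokine gene Osm (-1.97 ± 0.71) and the kinase gene Pim3 (-1.89 ± 1.01) were others, and each of the 4 had an adjusted p = 0.0348. That list was not called (median -0.51 relative to all genes, camera adjusted p = 0.0714).

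The list of FGF receptors and ligands was called upward relative to the other genes (median 0.96 above that of all genes, camera adjusted p = 0.00580), and lost the call (adjusted p = 0.725 with an estimated correlation). Of 9 tested members 3 rose, the ligand genes Fgf9 (1.75 ± 0.96, adjusted p = 0.0366) and Fgf2 (1.56 ± 0.48, adjusted p = 0.0405) and the receptor gene Fgfr2 (1.66 ± 0.52, adjusted p = 0.0365), 3 also when adjusted over the list alone. In DMSO Fgf2 and Fgfr2 were under 0.5 FPKM in all 3 lines and Fgf9 was at 1.19, 0.146 and 0.771 FPKM in BBC, ZNF and BCRF8C. Fgfr2 went from 0.403 to 2.12 FPKM in BBC, from 0.102 to 4.07 in ZNF and from 0.125 to 2.48 in BCRF8C. Fgfr3 (1.14 ± 0.64) did not pass (adjusted p = 0.0836). The list was not called after quantile normalization (adjusted p = 0.113), with the expression trend removed (0.195) or without BCRF8C (0.112).

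Genes for growth and replication fell together. MYC and its targets fell in 22 of 24 members (24 when adjusted over the list alone), with a median of -1.53 relative to that of all genes. Among them were Ldha, the enzyme gene that makes lactate (-2.92 ± 1.37), the DNA repair endonuclease gene Apex1 (-2.70 ± 1.64), Fbl, which encodes the nucleolar protein fibrillarin (-2.61 ± 1.20), and the nucleotide kinase gene Nme1 (-2.51 ± 1.04), each with adjusted p = 0.0348. Of 23 ribosome biogenesis genes 22 fell (23 when adjusted over the list alone; median -1.14 relative to all genes), including Bop1 (-2.68 ± 1.39), Nop2 (-2.66 ± 1.51) and Nop16 (-2.50 ± 1.22). Of 24 S phase genes 21 fell, and 21 when adjusted over the list alone (median -1.07 relative to all genes). Mcm5 (ENSMUSG00000005410, chromosome 8, 77633427 to 77652338), a subunit of the replicative helicase, went from 86.9 to 13.6 FPKM in BBC, from 181 to 62.5 in ZNF and from 139 to 25.5 in BCRF8C (-2.17 ± 0.57), beside Mcm2 (-2.33 ± 0.99) and Mcm3 (-2.15 ± 0.56). Camera gave an adjusted p = 9.60e-05 for each of these 3 lists, and each lost the call (adjusted p = 0.725 with an estimated correlation).

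The list of G2 and mitosis genes fell in 16 of 20 members (18 when adjusted over the list alone), among them Cdc20, an activator of the anaphase-promoting complex (-2.26 ± 0.82), the mitotic kinase gene Cdk1 (-1.93 ± 0.65), Birc5 (-1.90 ± 0.10) and Bub1b (-1.78 ± 0.10). Its median was -0.84 relative to all genes, with a camera adjusted p = 0.000710 and an adjusted p = 0.725 with an estimated correlation. The call ended after quantile normalization (0.224), with the expression trend removed (0.381) and, narrowly, at a mean FPKM of at least 5 (0.0523).

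Genes of metabolic supply were among the lowest. In the list of ATF4 targets and amino acid supply genes 17 of 20 fell (18 when adjusted over the list alone). Asns (ENSMUSG00000029752, chromosome 6, 7625169 to 7643254), which encodes asparagine synthetase, went from 61.4 to 5.03 FPKM in BBC, from 142 to 31.0 in ZNF and from 37.0 to 4.20 in BCRF8C (-2.80 ± 0.61). Shmt2 (-3.04 ± 1.20) and Mthfd2 (-2.63 ± 0.54), enzymes of mitochondrial folate metabolism, and Atf4 itself (-2.79 ± 0.66), the transcription factor of the amino acid response, also fell, all with adjusted p = 0.0348. The list median was -1.50 relative to all genes (camera adjusted p = 0.000101; adjusted p = 0.725 with an estimated correlation). In the cholesterol synthesis list 19 of 20 genes fell (20 when adjusted over the list alone). Fdps (ENSMUSG00000059743, chromosome 3, 88897514 to 88905881), which makes farnesyl diphosphate, went from 83.9 to 10.4 FPKM in BBC, from 76.6 to 14.4 in ZNF and from 78.1 to 3.22 in BCRF8C (-3.15 ± 0.97), and Mvd (-2.31 ± 0.66) and Sc4mol (-2.25 ± 0.12) fell with it. The list median was -1.17 relative to all genes (camera adjusted p = 3.21e-05; adjusted p = 0.725 with an estimated correlation). Glycolysis genes fell in 16 of 17 members, and 16 when adjusted over the list alone, with Eno1 (-2.92 ± 1.22), Pgam1 (-2.88 ± 1.38) and Aldoa (-2.80 ± 1.22) beside Ldha. The list median was -1.51 relative to all genes (camera adjusted p = 0.000872; adjusted p = 0.725 with an estimated correlation). The lists for MYC, ribosome biogenesis, S phase, glycolysis, cholesterol and ATF4 were called downward also after quantile normalization, with adjusted p from 4.97e-07 for ATF4 to 0.000138 for S phase, and with the expression trend removed, from 8.90e-08 for ATF4 to 0.000162 for S phase. With the trend removed these calls too were lost, at adjusted p = 0.424 with an estimated correlation for cholesterol and ATF4 and adjusted p = 0.571 with an estimated correlation for the other 4, and 0 single members passed.

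Survival and stress genes moved in single members. Of all 14232 genes tested 4295 fell, and the counts of falls in the lists of this paragraph are near or below that share. In the BCL2 family 4 of 12 fell, 4 also when adjusted over the list alone: the survival gene Bcl2 (-2.31 ± 1.73, adjusted p = 0.0385), which went from 79.2 to 3.11 FPKM in ZNF, and the death effector and sensitizer genes Bax (-2.24 ± 1.20, adjusted p = 0.0348), Bak1 (-1.94 ± 0.92, adjusted p = 0.0348) and Bad (-1.55 ± 1.01, adjusted p = 0.0399). Of 16 p53 targets 3 fell, Bax, the exonuclease gene Aen and the stress gene Sesn2, 2 when adjusted over the list alone. Of 18 FOXO targets, 3 fell, among them Bnip3 and Gabarapl1, and 1 rose, the recombinase gene Rag1 (1.06 ± 0.28, adjusted p = 0.0388). When adjusted over the list alone, 0 passed. Rag1 went from 0.360 to 1.69 FPKM in BBC, from 272 to 482 in ZNF and from 0.001 to 1.59 in BCRF8C. In BBC and BCRF8C it was thus among the entries nearly silent in DMSO that were above 1 FPKM with BGJ398. Its ratios with the expression trend removed were 0.51 in BBC, 1.72 in ZNF and 0.49 in BCRF8C, without passing. The interferon list had 4 of 16 lower, among them Bst2, Ifi47 and Irf9 (3 when adjusted over the list alone). Among 12 NF-kB targets the cytokine gene Tnf (-2.89 ± 1.23, adjusted p = 0.0348) and Nfkb1 (-1.57 ± 0.38, adjusted p = 0.0348) fell, 2 also when adjusted over the list alone. Camera called none of these lists (adjusted p = 0.851 for the BCL2 family, 0.288 for p53, 0.491 for FOXO, 0.381 for interferon and 0.675 for NF-kB). For p53 and FOXO it gave an upward direction beside medians of -0.26 and -0.35 and means of -0.24 and -0.25, and for NF-kB a downward one beside a median 0.28 above that of all genes. The FOXO list was called upward with the expression trend removed (adjusted p = 0.0353; adjusted p = 0.571 with an estimated correlation).

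Lists of lineage, antigen presentation and receptors were not called either, and no more than 2 members of each changed. The changed members were H2-DMa (down) of 8 MHC class II genes, Dtx1 (1.08 ± 0.10, up, adjusted p = 0.0353) of 9 Notch targets, Ifngr1 (-1.85 ± 1.08, down) of 10 mast cell and cytokine receptor genes, Rag1 (up) of 19 B lineage markers and Sdc1 (down) of 8 plasma cell genes. In 3 further lists the members were named after their values were seen: Cd8a (1.14 ± 0.45, up) of 15 T lineage markers, Gp1bb (1.66 ± 0.73, up) of 5 erythroid, megakaryocyte and mast cell markers, and Hoxa10 (1.65 ± 0.63, up) with Bmi1 (down, adjusted p = 0.0436, but a log2 ratio of 0.0405 and adjusted p = 0.909 with the expression trend removed) of 11 stem and progenitor markers. When adjusted over each list alone, 0 members passed in these lists, except for 1, Gp1bb, in the erythroid list. Rag1 was nearly silent in DMSO in BBC and BCRF8C, as stated above. Camera adjusted p was 0.785 for MHC class II, 0.109 for Notch, 0.851 for receptors, 0.0523 for B lineage, 0.938 for plasma cells, 0.288 for T lineage, 0.156 for the erythroid list and 0.0839 for stem cells. Median and mean were below 0 and the direction upward for MHC class II, receptors, T lineage and plasma cells, and for the B lineage and erythroid lists the median was below 0, with the mean and the direction above. The B lineage list was called upward in some other settings with the preset correlation, and as deposited it had an adjusted p = 0.725 with an estimated correlation. Of its members, 19 had a mean of at least 1 FPKM in BBC, but 6 in ZNF and 6 in BCRF8C. Members listed at 0 in both libraries of a line, such as Igll1 and Cd79b in ZNF and BCRF8C, entered the test with a ratio of 0. That lies above the median of all genes (-0.69), so such pairs can raise the list. Among genes listed in all 3 lines, where no such pair enters, it was called upward too (camera adjusted p = 0.00473). With the expression trend removed it was not called there (camera adjusted p = 0.0940), nor among all tested genes (0.153). Of the myeloid list 4 members could be tested and of the stromal list 3, fewer than the 5 that camera required here. None of the 4 myeloid genes passed, and of the stromal ones Col1a1 rose (1.77 ± 1.20, adjusted p = 0.0449), from 0.941 to 4.39 FPKM in BBC, from 0.336 to 1.24 in ZNF and from 0.0109 to 7.66 in BCRF8C.

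Within single lines, where 1 library stands for each agent and no test was possible, genes went far apart in both directions. In BBC, Tlr13, a receptor gene for bacterial RNA, went from 0.361 to 37.7 FPKM and Il5ra, an interleukin receptor gene, from 3.27 to 14.5 FPKM. The interferon-induced GTPase gene Iigp1 went from 171 to 5.72, the surface antigen gene Ly6a from 293 to 14.5 and the purine salvage gene Aprt from 91.1 to 3.18 FPKM. In ZNF, Xkrx went from 2.44 to 93.4, Alox5ap, which serves leukotriene synthesis, from 1.06 to 35.2 and Lrrn2 from 0.0804 to 13.1 FPKM. Bcl2, the intermediate filament gene Vim (138 to 7.02), the noncoding RNA H19 (122 to 6.90), Gmppb (47.1 to 2.56), Akr1c13 (593 to 52.3) and the tubulin gene Tubb3 (88.7 to 7.44) were lowest relative to DMSO. In BCRF8C, Mid1, Tlr13 (0.0128 to 26.9 FPKM) and Zfp488 (9.78 to 253 FPKM) were among the highest ratios. There 6 Hist1 genes had the lowest, with Hist1h4f at 230 and 4.08 FPKM. The remaining named ratios of BBC were higher for Rabepk (listed at 0 and at 156 FPKM), Adamts7 (1.32 to 9.37), Vmn1r58 (12.4 to 48.1) and Hsd3b2 (12.3 to 47.6), and lower for Uck2 (661 FPKM and listed at 0), Dctpp1 (112 to 4.35) and Arhgap27 (94.5 to 3.78). The Uck2 entry is a short locus (chromosome 1, 169153958 to 169154050) and the Rabepk entry shares its place with another of the same name, so both are uncertain.

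Of 14765 genes in BBC, 1298 were at least 2-fold higher and 6637 at least 2-fold lower with BGJ398. In ZNF the counts were 1635 and 2020 of 12417, and in BCRF8C 3000 and 6012 of 13814, with median log2 ratios of -0.87, -0.48 and -0.80 in the 3 lines. With the expression trend removed they were 1848 and 1721 in BBC, 1210 and 690 in ZNF and 1962 and 1908 in BCRF8C.

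Set against 10000 random lists of like expression, which carry the same trend, the ATF4 and cholesterol lists were below the 2.5th percentile in each line. The ATF4 list had medians of -2.21, -1.66 and -2.45 in BBC, ZNF and BCRF8C against -1.22, -0.68 and -1.20 for the random lists, and the cholesterol list -2.11, -1.39 and -2.23 against -1.29, -0.63 and -1.28. Glycolysis (percentiles 0, 2.23 and 0.01) and ribosome biogenesis (0, 1.57 and 0) were below in all 3 lines as well. MYC targets were below in BBC and BCRF8C (0 and 0.02) and at percentile 17.3 in ZNF. S phase genes were below in BBC and ZNF (0.04 and 0) and at 6.93 in BCRF8C, whereas G2 and mitosis genes were below in ZNF (0; median -1.68 against -0.80) and at 92.2 and 82.4 in BBC and BCRF8C. The p53 and FOXO targets lay above the 97.5th percentile in BBC (99.4 and 98.2) and ZNF (100 and 100) and at 72.7 and 81.4 in BCRF8C. ERK feedback genes stood at 22.0, 4.36 and 1.09, STAT5 targets at 55.9, 2.08 and 1.55, and interferon genes at 11.7, 0.41 and 93.1 in BBC, ZNF and BCRF8C. In BCRF8C the ERK list came inside the range at pseudocount 5 (3.45), with no filter (3.06) and after quantile normalization (4.73). In ZNF it went outside at pseudocount 5 (1.795). STAT5 targets came inside in BCRF8C at pseudocount 5 (3.88) and in ZNF at pseudocount 0.1 (2.96), and interferon genes in ZNF at pseudocount 5 (7.095). FGF receptors and ligands were at 60.8, 57.3 and 45.3, inside the range of lists of like expression. The BCL2 family was at 97.9, 93.8 and 73.5, NF-kB targets at 98.5, 80.6 and 63.4, Notch targets at 97.3, 99.9 and 72.7, stem cell markers at 93.8, 19.5 and 98.7, B lineage markers at 97.4, 86.4 and 11.4, T lineage markers at 73.9, 71.3 and 88.6, MHC class II genes at 84.1, 11.8 and 32.5, and cytokine receptors at 37.5, 11.6 and 35.6. Plasma cell genes, at 99.9 in BBC and 21.5 in BCRF8C, and erythroid markers, at 63.5 in BBC, had too few members elsewhere. In all, 11 lists in BBC, 11 in ZNF and 8 in BCRF8C lay outside the range, and whether the lines differed was not tested. With the expression trend removed, FOXO, p53 and BCL2 family genes in BBC (97.0, 94.9 and 86.3) and ribosome biogenesis in ZNF (4.28) came inside the range. B lineage markers in BBC and ZNF (99.9 and 98.9), cytokine receptors in ZNF (0.56) and Notch targets and T lineage markers in BCRF8C (98.3 and 99.3) went outside it.

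**Figure D3:**
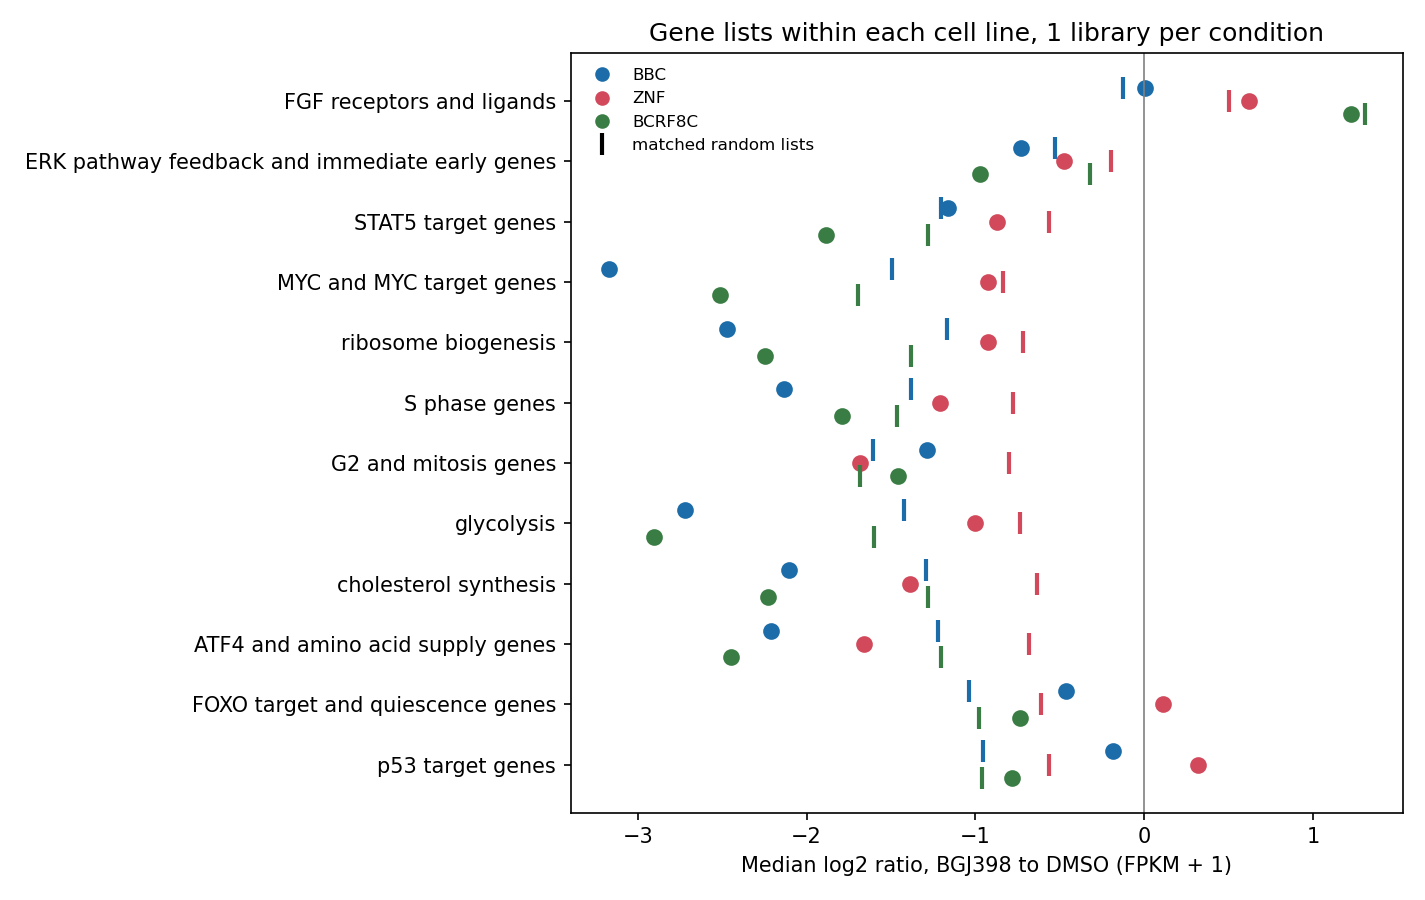
Median log2 ratio of BGJ398 to DMSO (horizontal axis, log2(FPKM + 1) scale) of 12 gene lists (vertical axis) in BBC, ZNF and BCRF8C, shown as coloured points, beside the median of random lists matched on expression, shown as vertical marks. The points of the ATF4 and cholesterol lists lie left of their marks in all 3 lines, and the p53 points lie right of theirs (-0.18, 0.32 and -0.78 against -0.96, -0.56 and -0.96).

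Ratios of different lines were correlated. Across genes, which are not independent replicates, the log2 ratios of BBC and ZNF had a Pearson correlation of 0.456 (Spearman 0.693), those of BBC and BCRF8C 0.545 (0.747) and those of ZNF and BCRF8C 0.562 (0.696). With the expression trend removed the Pearson correlations were 0.322, 0.366 and 0.381. In all 3 lines 528 genes were at least 2-fold higher and 1441 at least 2-fold lower, where independent lists would share 29.5 and 398. With the trend removed 481 and 120 did so, against 25.0 and 9.08. The lines share no library, but all 3 ratios share the narrower range of the BGJ398 libraries.

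Some genes went opposite ways. Between BBC and ZNF, 132 genes were at least 2-fold apart in opposite directions, between BBC and BCRF8C 166, and between ZNF and BCRF8C 121. The ETS factor gene Etv4, a target of ERK signalling, went from 10.3 to 0.484 FPKM in BBC and from 17.5 to 2.28 in BCRF8C, and from 0.342 to 5.29 in ZNF. Pax5 (ENSMUSG00000014030, chromosome 4, 44544017 to 44724318), the B lineage commitment factor, went from 84.7 to 25.2 FPKM in BBC, from 0.215 to 4.66 in ZNF and from 0.0518 to 1.60 in BCRF8C. The haematopoietic factor genes Lmo2 (39.7 to 9.34, 0.150 to 2.28 and 0.0778 to 2.07 FPKM) and Bcl11a (33.5 to 9.59, 0.0824 to 1.21 and 0.390 to 4.95 FPKM) had the same pattern. With the expression trend removed Pax5 (-0.03 in BBC), Lmo2 (-0.54 in BBC) and Bcl11a (-0.28 in BBC) were no longer 2-fold apart in opposite directions. The amino acid carrier gene Slc7a3 went from 15.8 to 4.11 FPKM in BBC, from 33.7 to 5.64 in ZNF and from 0.237 to 5.04 in BCRF8C.

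The 3 lines differed in lineage markers irrespective of the agent. BBC carried early B lineage transcripts: Vpreb3 was at 1088 FPKM in DMSO and 560 FPKM with BGJ398, Igll1 at 546 and 252, Cd79b at 232 and 140, and Vpreb1 at 171 and 92.6. Igll1, Cd79b and Vpreb1, parts of the pre-B and B cell receptors, were listed at 0 in all libraries of the other lines. ZNF carried T lineage transcripts, with the CD3 chain genes Cd3g (335 and 186 FPKM) and Cd3d (119 and 68.8) and the T cell factor gene Tcf7 (217 and 128). Rag1 (272 and 482 FPKM) and Dntt (264 and 260), genes of antigen receptor rearrangement, were also high there. Lck, a T cell kinase gene, was at 161 and 131 FPKM in ZNF and at 28.6 and 27.5 in BBC, and Lat at 386 and 245 in ZNF and 145 and 76.2 in BBC. BCRF8C had the chemokine receptor gene Ccr2 (487 and 245 FPKM), the metallothionein genes Mt2 (1774 and 285) and Mt1 (1645 and 1121), P2ry14 (145 and 61.4), Tnfrsf9 (472 and 59.7) and the killer cell lectin gene Klrd1 (52.8 and 34.5). Of 20 myeloid markers 7 had an entry in the table and the others were not analysed here; of those with an entry, Fcgr3 was at 44.7 and 28.9 FPKM and Cd68 at 6.14 and 5.80 FPKM in BCRF8C. Ly6a, a stem and progenitor surface antigen, was at 831 and 329 FPKM there.

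By the rule of at least 10 FPKM in both libraries of a line and at least 10-fold above the other 4 libraries, 60 genes were specific to BBC, 13 to ZNF and 12 to BCRF8C. Further genes named by it were Ly6d (936 and 519 FPKM) and Igj (248 and 237) for BBC and Endou (137 and 109) and Arsi (61.3 and 40.4) for ZNF. The table held genes above about 1.02 FPKM in a BBC library, apart from 14 at 0 there, so the count for BBC is favoured. Genes without an entry, such as Cd3e, Cd4 and Rag2, were not analysed here. Erythroid and platelet markers were low where listed, with Hbb-b1 at 20.5 and 8.28 FPKM and Pf4 at 7.79 and 1.81 FPKM in BBC and both listed at 0 in the other lines. The class II chaperone gene Cd74 was at 196 and 26.1 FPKM in BBC and at 49.1 and 15.6 in BCRF8C, and was listed at 0 in ZNF.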

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

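These genes stand out because 2 lines went at least 2-fold in opposite directions. The differences between lines were not tested, since each line has 1 library per agent, and the limits on the table and the range of values in the report apply to them. Values with the expression trend removed were added after seeing the data. Log2 ratios of BGJ398 to DMSO are given in the order BBC, ZNF and BCRF8C, on the log2(FPKM + 1) scale.

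The ETS factor gene Etv4 had ratios of -2.93, 2.23 and -2.50, and -2.44, 1.95 and -1.48 with the expression trend removed. The B lineage factor gene Pax5 had -1.71, 2.22 and 1.31, and -0.03, 1.79 and 0.36 with the trend removed, so that the BBC ratio was close to that of genes of like expression. The haematopoietic factor genes Lmo2 (-1.98, 1.51 and 1.51) and Bcl11a (-1.70, 1.03 and 2.10) were high in BBC in DMSO and nearly silent in ZNF and BCRF8C, with at most 0.390 FPKM there. With the trend removed they had -0.54, 0.67 and 0.39, and -0.28, 0.38 and 1.41, so neither these genes nor Pax5 stayed 2-fold apart in opposite directions. The carrier genes Slc43a3 (-1.73, -1.27 and 2.21) and Slc7a3 (-1.72, -2.39 and 2.29) were lower in BBC and ZNF and higher in BCRF8C, where their DMSO values were 0.0219 and 0.237 FPKM. With the trend removed Slc43a3 had -0.06, -0.53 and 1.07, and Slc7a3 -0.56, -1.75 and 1.47.

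Snhg9, a host gene of a small nucleolar RNA, had ratios of -1.50, 2.49 and -5.05, with the floor value of 0.001 FPKM in the ZNF library of DMSO and the BCRF8C library of BGJ398. The leukotriene receptor gene Ltb4r1 went from 0.001 to 4.92 FPKM in ZNF (2.56) and from 17.4 to 2.30 in BCRF8C (-2.48). With the trend removed Snhg9 had -0.41, 1.91 and -4.30, and Ltb4r1 2.02 in ZNF and -1.47 in BCRF8C. The pseudogene Rps15-ps2 had -2.18 in BBC and 1.84 in BCRF8C, from 0.001 to 2.59 FPKM, and the receptor pseudogene Vmn1r-ps149 -1.88 in BBC, where it was listed at 0 with BGJ398, and 2.35 in ZNF. Reads of these pseudogenes can be shared with other copies, so both values are uncertain. With the trend removed Rps15-ps2 had -1.01 in BBC and 0.68 in BCRF8C, and Vmn1r-ps149 -2.35 in BBC and 1.70 in ZNF.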

How the results depend on the processing

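All settings that use genes listed in all 3 lines or remove the expression trend were chosen after seeing the data. Among genes listed in all 3 lines, 7166 of 12866 passed in limma as deposited (77.1% downward). The count of 5236 changed genes (82.0% downward) stayed within 1.5 times under the other pseudocounts and filters, without the intensity trend, with robust estimation and with the ratio limit, from 4566 to 6378, and its downward share was 94.0% at a mean FPKM of at least 5. It did not under other scalings: 14 genes (7.14% downward) after median-of-ratios scaling, 3 (33.3%) after quantile normalization, 0 with the expression trend removed (smallest limma adjusted p 0.0597; 3084 genes at an unadjusted p under 0.05), 366 (13.7%) with the trend removed among listed genes and 394 (13.2%) after quantile normalization among listed genes. Without the line as a block, that is without the pairing, 7 genes passed (14.3% downward). Leaving out 1 line gave from 0 to 4974 genes: 0 without BBC (2991 at an unadjusted p under 0.05), 4974 without ZNF (96.4% downward) and 1648 without BCRF8C (51.7%). The cause was not tested, except that fewer lines leave fewer samples. Of the named genes that had passed, 85 no longer did after median-of-ratios scaling, 85 after quantile normalization, 85 without the block and 85 without BBC. Since 0 genes passed without BBC, these 85 were all the named genes that had passed. None of them passed with the trend removed either, where 84 kept their sign and 1, Bmi1, did not. The ratio of Bmi1 turned to 0.0405 with the trend removed and to 0.0475 with it removed among listed genes, and the cause was not tested.

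Of the 8 list calls, 0 held with an estimated correlation in camera (adjusted p = 0.725 for each of the 8) and 0 in fry, which asks whether a list moves 1 way: 0.327 for FGF receptors, 0.185 for MYC, ribosome biogenesis and glycolysis, 0.148 for S phase, 0.0840 for G2 and mitosis and for ATF4, and 0.141 for cholesterol. Camera with an estimated correlation tests on 2 residual degrees of freedom and had little power here. With the preset correlation, from 6 to 10 lists were called over the other settings. FGF receptors lost the call after quantile normalization (0.113), without BCRF8C (0.112), with the trend removed (0.195) and with it removed among listed genes (0.215). G2 and mitosis lost it at a mean FPKM of at least 5 (0.0523), after quantile normalization (0.224), with the trend removed (0.381) and with it removed among listed genes (0.509). Calls were gained by B lineage markers at pseudocount 0.1 (0.00727), at a mean FPKM of at least 5 (3.98e-07), after median-of-ratios scaling (0.0440), without BBC (0.00397) and among listed genes (0.00473). STAT5 targets gained one with no filter (0.0138) and without BBC (0.0220), Notch targets (0.00192) and T lineage markers (0.00349) at a mean FPKM of at least 5, stem cell markers without the block (0.0472) and FOXO targets with the trend removed (0.0353; adjusted p = 0.571 with an estimated correlation). The cause was not tested. The block changed no other list call.

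Counts within a line moved with each choice. Genes at least 2-fold higher in BBC numbered 2224 at pseudocount 0.1, 381 at pseudocount 5, 437 at a mean FPKM of at least 5, 3520 after median-of-ratios scaling and 2280 after quantile normalization, 548 at 3-fold and 2419 at 1.5-fold; those lower numbered 1836 after median-of-ratios scaling, 2625 after quantile normalization, 1721 with the trend removed and 3529 at 3-fold. In ZNF those higher were 536 at pseudocount 5, 2487 with no filter and 388 at a mean FPKM of at least 5, and those lower 1168 at pseudocount 5, 710 after median-of-ratios scaling, 756 after quantile normalization, 690 with the trend removed, 433 at 3-fold and 5371 at 1.5-fold. In BCRF8C those higher were 704 at pseudocount 5, 466 at a mean FPKM of at least 5 and 1962 with the trend removed, and those lower 2216 after median-of-ratios scaling, 2881 after quantile normalization, 1908 with the trend removed and 3361 at 3-fold.

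Genes higher in all 3 lines numbered 1182 at pseudocount 0.1, 93 at pseudocount 5, 164 at a mean FPKM of at least 5 and 1525 after median-of-ratios scaling, and those lower 810 at pseudocount 5, 201 after median-of-ratios scaling, 185 after quantile normalization, 120 with the trend removed and 108 with it removed among listed genes. The Pearson correlation of BBC and ZNF was 0.352 at a mean FPKM of at least 5, 0.335 after quantile normalization, 0.322 with the trend removed and 0.643 among listed genes. That of BBC and BCRF8C was 0.474 at pseudocount 0.1, 0.432 at a mean FPKM of at least 5, 0.485 after median-of-ratios scaling, 0.420 after quantile normalization, 0.366 with the trend removed and 0.739 among listed genes. For ZNF and BCRF8C it was 0.453 at a mean FPKM of at least 5, 0.387 after quantile normalization, 0.381 with the trend removed, 0.683 among listed genes and 0.483 with both. Genes specific to BBC numbered 27 at pseudocount 5, 35 at 50 FPKM and 100 at 4-fold, those specific to ZNF 45 at 4-fold, and those specific to BCRF8C 4 at pseudocount 5, 6 at 50 FPKM, 21 after quantile normalization and 47 at 4-fold. Of the list placements within a line, 9 crossed the range at pseudocount 5, 9 with the trend removed and 7 after quantile normalization, ribosome biogenesis in ZNF among them in each case (12.8, 4.28 and 4.68), and 3 or fewer in each other setting. For these counts, correlations and placements the cause was not tested. Depth is unknown, so what it limits could not be computed.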

Other observations

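Tests of the expression trend, of 1 scaling factor, of shallow sequencing, of background reads and of paralogs were chosen only after the result was seen, as were the gene groups of the first 2 paragraphs below. The splits of the samples and the tests of length with GC content and of RNA without poly(A) tails were chosen before.

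Genes of cytosolic ribosomal proteins were lower with BGJ398 in 77 of 78 members in BBC, 76 of 77 in ZNF and 77 of 77 in BCRF8C, with median log2 ratios of -1.997, -0.76 and -2.66. Their median values went from 874 to 219 FPKM, from 990 to 574 and from 806 to 118. With the expression trend removed the medians were -0.24, 0.01 and -0.37, so their fall as deposited was close to that of other abundant genes, and its sign in ZNF depended on that trend. Replication-dependent histone genes stood apart from it, at -2.69, -1.65 and -3.52 as deposited and -1.01, -0.90 and -1.82 with the trend removed.

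The 12 mitochondrial mRNAs did not follow the other abundant transcripts. Their summed values went from 21536 to 11719 FPKM in BBC, from 36035 to 45091 in ZNF and from 82224 to 103937 in BCRF8C. Median log2 ratios were -0.66, 0.43 and 0.60, and with the trend removed 0.996, 1.11 and 3.26, which turns the sign in BBC. 

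For the narrower range of expression in the 3 BGJ398 libraries a single scaling factor per library is argued against. After median-of-ratios scaling the lowest and highest expression classes still differed by 1.77 in BBC, 1.55 in ZNF and 2.69 in BCRF8C. The limit for listing enlarges the medians of the lowest class and so these differences. In the class from 2 to 3 the scaled medians were 0.14, -0.02 and 0.13, against -0.56, -0.45 and -1.24 in the highest. Shallow sequencing alone is argued against, because the most abundant genes were lower in each line, with medians of -1.71, -0.89 and -2.25. Reads from a background source in the BGJ398 libraries may contribute: olfactory and vomeronasal receptor genes, silent in most blood cells, were higher there in 483 of 506 listed in BBC (95.5%, Clopper-Pearson lower bound 93.3%), 264 of 265 in ZNF and 468 of 468 in BCRF8C, against 71.1%, 77.7% and 72.9% of other genes matched on the larger of the 2 values. A gene is listed if either library of the line reaches the limit, and these genes are in part those counted in the report as nearly silent in DMSO, so the test is not independent of the pattern. For receptor genes with a mean of at least 1 FPKM in a line (224 in BBC, 40 in ZNF and 313 in BCRF8C), median log2 ratios with the expression trend removed were 0.23, 0.23 and 0.28. With length and GC content removed as well they were -0.18, 0.33 and -0.12, so no rise beyond like genes held in all 3 lines. An effect of FGFR inhibition on the RNA of the cells was not tested and stays open, since agent and library coincide in every line.

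Cholesterol synthesis and ATF4 lists were lower in each line. The expression trend alone is argued against, because with it removed the 6 medians of these lists lay between -1.26 and -0.72. Both lists had already lain below random lists of like expression in each line, so this repeats that comparison in the same libraries. Transcript length and GC content are argued against as well, since with trend, length and GC removed the highest of the 6 was -0.78. A response of these supply genes to FGFR inhibition is a hypothesis that may account for it, and it was not tested, since agent and library coincide.

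Histone genes were the largest falls among the called genes that could be named. The expression trend alone is argued against by the median of -0.90 in ZNF, the highest of the 3 lines with the trend removed. Reads moved between paralogs are argued against only for the fall as deposited. The summed values of all histone genes had log2 ratios of -2.80, -1.66 and -3.53 in BBC, ZNF and BCRF8C. The trend was not removed from these sums, and those of the abundant ribosomal protein genes were -1.94, -0.72 and -2.59. Whether the histone sums fell beyond the trend was not tested. A loss of RNA without poly(A) tails stays open. Relative to all genes, small nuclear and nucleolar RNAs stood at 0.47 in BBC, 0.44 in ZNF and -1.11 in BCRF8C, in different directions. These values carry the expression trend. With it removed their medians were 0.65, 0.59 and -0.25, the last with an interval from resampled genes of -0.55 to 0.14. No line thus showed a clear fall beyond the trend. With length and GC content removed as well they were -0.04, -0.36 and -0.07, and the ZNF interval lay below 0 (-0.52 to -0.11). Fewer cells in S phase, which would lower histone transcripts, may also account for the histone falls and stays open. The S phase list was at percentiles 0.04 in BBC, 0 in ZNF and 6.93 in BCRF8C of matched lists. The last lay inside the range as deposited and in the other settings except quantile normalization (1.25).

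Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 5236 changed genes and the highest other 223; 1 of the 10 gave as many genes. For gene lists the real split gave 8 calls and the highest other 10, and 3 of the 10 gave as many. Among the 4 splits that part all 3 line pairs, the highest other values were 17 genes and 7 lists, and the other splits keep both libraries of a line on 1 side.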
